A study of Mus musculus with 12 samples.

How the data were processed

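Bulk RNA-seq of whole mouse skin was analysed in 12 samples, 3 in each of 4 groups given by genotype and skin state. Per the labels, RNA was extracted with an RNeasy Fibrous Tissue kit, amplified to cDNA from 10 ng of total RNA with the Smart-Seq v4 kit, and made into libraries with Nextera XT. This kit does not mark the strand, so the counts of overlapping and antisense genes cannot be told apart. The deposited values were raw read counts per Ensembl gene, with 1 library per column per the file headers. They were checked to be whole numbers at or above 0 with library totals that differ, so no scaling by the authors was seen in them. Per the submitters' processing notes, STAR 2.5.2b, SAMtools, HTSeq 0.5.3, DESeq2 and HOMER were used with the mouse build mm10, without the role of each tool. The annotation version and the strand setting are not given in the sources used here. Columns repeated between the deposited tables were equal and were read once, and 1 column that belongs to no listed sample was not used here.

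Each table held 53379 gene IDs, of which 53274 matched GENCODE M21 (GRCm38, the same assembly as mm10), the source of symbols, coordinates and exonic lengths. The 105 unmatched IDs held at most 0.0454% of the counts of any library, and 49676 genes had a count in at least 1 library. Library totals ran from 8817013 to 16809687 counts. The labels number 3 samples per group but do not say that they are separate animals, so every p-value measures the spread between these samples. Within groups, the chi-square per degree of freedom between pairs of libraries ran from 11.4 to 102 over 12 pairs, so no library repeats another. Reads carry no molecular identifiers, so count intervals and floors cover counting error only. A fold against a group with 0 counts was computed against a floor of 3 counts over the whole group and is a lower bound. With 1 to 3 counts in a group, the ratio of pooled CPM (counts scaled to a common library total) is given with its 95% exact counting interval.

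All 12 libraries were fitted together in edgeR 4.0.16 with 4 group means, TMM scaling, the default expression filter with a count minimum of 10, and a robust quasi-likelihood F test, 2-sided. Over the 23635 genes that passed the filter, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at adjusted p under 0.05. The contrasts were injury in control skin, injury in Nf1-KO skin, Nf1-KO in uninjured skin, Nf1-KO in injured skin, and the difference between the injury responses. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries unless raw CPM is stated. Nf1 was also compared by a 2-sided exact permutation test of log2 CPM, which cannot go below p = 0.1 with 3 against 3. The agreement of both injury responses was measured by Pearson and Spearman correlation across genes, which are not independent replicates.

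Gene lists were taken from textbook markers: 29 were fixed and 27 tested, the mitochondrial and sex-marker lists serving as checks. They cover the growing hair follicle, basal, differentiating and wound-activated keratinocytes, sebaceous gland, melanocytes, adipocytes, skeletal muscle, interstitial matrix and myofibroblasts. They also cover blood and lymphatic endothelium, red blood cells, macrophages, dendritic cells with MHC class II, neutrophils, mast cells, T and natural killer cells, and B and plasma cells. The remaining lists hold myelin, other Schwann lineage genes, axon, cell cycle, RAS and ERK output, cytokines, interferon response, and immediate early and heat shock genes. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, which compares a list with all other genes, adjusted over the 27 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves one way without reference to other genes, were the alternatives.

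The contrasts, tests, lists, rule for named genes and most of the alternative settings were fixed before the data were examined. Named genes were, per comparison, up to 8 with the largest rise and up to 8 with the largest fall. These had to be called, to average at least 2 CPM over all libraries, to show no overlap between the groups, and to have a symbol that is no Gm number, Rik clone, pseudogene or predicted model. Up to 3 called members with the smallest p per list were added, or the member with the smallest p where none was called, together with Nf1 and Prss56. For the interaction, the 10 genes with the smallest p were named, and genes named outside the rule are said to have been chosen after their values were seen. Of the genes that the rule names, the text gives a selection made after their values were seen, and the others are not reported here. The settings fixed in advance were median-of-ratios scaling, no filter, a filter of 2 CPM in 3 samples, a replicate block, a fit of the compared groups alone, limma voom, DESeq2 1.42.0 (on all genes with a count, with its own independent filter), a 2-fold minimum, and leaving out each library. A contrast over both skin states was added after seeing the data, as were subtraction of background, removal of the 2 libraries of highest background in each comparison, and a covariate for the ribosomal RNA-like share.

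Background was measured as counts over 1641 genes of the olfactory and vomeronasal receptor families (5127.8 kb of exons), after the top 5% were left out. Subtraction removed each library's density per kb times exonic length from every gene. The ribosomal RNA-like share is the share of counts in genes with ribosomal RNA or ribosomal RNA-like sequence, among them Lars2, Gm42418 and the mitochondrial ribosomal RNAs. The pipeline was tested on simulated data in which 200 of 23635 genes were changed, in equal parts by 2-fold and by 4-fold. Each gene's own dispersion was scaled up, never down, by its quasi-likelihood dispersion. The simulated spread may thus exceed that of the data, and the recovered shares may be too low. At 2-fold, it recovered 10% of changed genes for injury in control skin, 9% for injury in Nf1-KO skin, 9% for Nf1-KO in uninjured skin and 7% for Nf1-KO in injured skin. At 4-fold, it recovered 56%, 51%, 59% and 62% in the same order, with 2, 4, 3 and 9 false calls. The false calls made up 2.94%, 6.25%, 4.2% and 11.5% of all calls. For Nf1-KO in injured skin, camera called 20 of 20 simulated lists of 20 genes raised 1.5-fold and 0 of 20 flat lists, where genes were simulated as independent. Replicate numbers were checked as a pairing: 5 of 18 same-numbered pairs of libraries correlated above 0.1, from -0.314 to 0.454, so the numbers do not pair the samples. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.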

Results

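RNA was measured in whole skin of 3-month-old mice, either uninjured or 14 days after injury. Control mice carried Prss56Cre with the R26tdTom reporter, and Nf1-KO mice carried in addition a floxed and a null Nf1 allele. Nf1 encodes neurofibromin, a negative regulator of RAS, and the series title names boundary cap cells, a source of Schwann cells, as the site of the knockout. The 12 samples form 4 groups of 3: control uninjured, Nf1-KO uninjured, control injured and Nf1-KO injured. Control uninjured libraries 1 to 3 held 8817013, 11221476 and 15521143 counts, and Nf1-KO uninjured libraries held 10064140, 11766127 and 11830734. Control injured libraries held 12681653, 16809687 and 16669630 counts, and Nf1-KO injured libraries held 16513258, 15239824 and 13072756.

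Sex markers, background and the ribosomal RNA-like share moved with skin state. Xist, the RNA that silences an X chromosome in female cells, stood at 0.709 to 2.95 raw CPM in the 6 uninjured libraries and at 436 to 627 in the 6 injured ones. The Y-linked helicase gene Ddx3y stood at 68.2 to 93.3 raw CPM in uninjured libraries and at 0 to 0.0595 in injured ones. Uninjured libraries thus carried male markers and injured libraries female markers, in both genotypes. Receptor families of the nose, which skin is not known to express, had 0.0792 to 0.282 CPM per kb in uninjured libraries and 0.00156 to 0.0425 in injured ones. Among injured libraries, Nf1-KO 3 (0.0425) and Nf1-KO 2 (0.0141) were highest. A count was seen for 38490 to 43311 genes per uninjured library and 25188 to 34592 per injured library. The ribosomal RNA-like share was 2.08% to 5.60% in uninjured skin. In injured skin it was 11.9%, 4.81% and 4.97% in control libraries 1 to 3, and 8.61%, 4.09% and 10.6% in Nf1-KO libraries 1 to 3. Mitochondrial transcripts made up 1.61% to 2.25% of counts in every library.

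**Figure D1:**
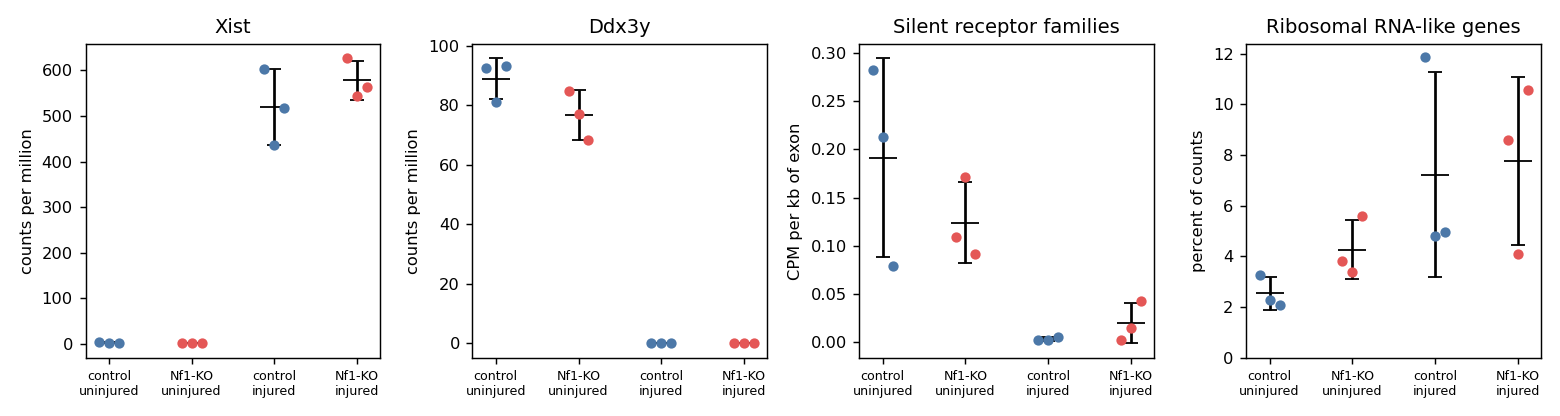
Raw CPM of Xist and Ddx3y, density of counts over receptor families of the nose (CPM per kb) and ribosomal RNA-like share (% of counts), by group, with points for libraries and bars for mean ± SD (n = 3). Xist is at most 2.95 CPM in uninjured and at least 436 CPM in injured libraries, and the receptor density is at least 0.0792 in uninjured and at most 0.0425 in injured libraries.

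The targeted gene, Nf1 (ENSMUSG00000020716, chromosome 11, 79339693 to 79581612, mm10), was detected in every library. Raw CPM in libraries 1 to 3 were 17.2, 13.7 and 9.41 in control uninjured skin and 9.94, 11 and 8.96 in Nf1-KO uninjured skin. They were 14.7, 8.98 and 10.6 in control injured skin and 10.1, 8.14 and 14.1 in Nf1-KO injured skin. In uninjured skin the mean was 9.98 ± 1.05 in Nf1-KO and 13.5 ± 3.92 in control (n = 3, log2 difference -0.39, exact permutation p = 0.3). In injured skin it was 10.8 ± 3.03 and 11.4 ± 2.98 (n = 3, log2 difference -0.09, exact permutation p = 0.7, smallest possible 0.1). In edgeR the log2 fold changes were -0.31 (adjusted p = 0.884) and -0.11 (adjusted p = 0.989). Counts per gene do not separate a recombined allele from an intact one. Whole skin also holds cells outside the recombined lineage, so these values do not check the genotype labels. As the genotype is written, the null allele does not depend on Cre, so cells outside that lineage would carry it too. The contrasts between genotypes therefore cannot separate an effect of the null allele in all cells from that of recombination in the lineage. Prss56 (chromosome 1, 87183313 to 87188405), whose promoter drives Cre, had 9, 12 and 3 counts in control uninjured libraries and 3, 10 and 1 in Nf1-KO uninjured ones. It had 0 counts in each control injured library and 0, 9 and 2 in Nf1-KO injured ones.

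Injured control skin, compared with uninjured control skin, had much higher levels of genes of the growing hair follicle. All 23 measured genes of the hair follicle list rose (23 adjusted over the list alone, as in every list for which no second count is given), with a median log2 fold change of 9.26. Krt71 (chromosome 15, 101733949 to 101743109), a keratin of the inner root sheath, went from 1.14 ± 0.583 to 6423 ± 1649 CPM (n = 3, 5489-fold). Krt27, of the same sheath, rose 3330.2-fold, and Krt31, a keratin of the hair cortex, rose 547-fold from 0.55 ± 0.15 to 299 ± 161 CPM. Msx2, a transcription factor of the hair matrix, rose 15.5-fold, and S100a3, a protein of the hair cuticle, rose 262-fold. Keratin-associated protein genes rose as well. Krtap8-1 reached 1108 ± 744 CPM (5849.5-fold), Krtap22-2 went from 0.099 ± 0.025 to 892 ± 767 CPM, and Krtap19-5 (chromosome 16, 88895968 to 88896457), with 0 counts in uninjured control skin, was at least 3610-fold higher. With 1 or 2 counts in uninjured skin, the ratio was 12700 (2270 to 500000) for Krtap6-5, 9510 (1710 to 376000) for Krtap19-3 and 7020 (1940 to 57900) for Krtap3-1. Camera called the list higher (adjusted p = 2.52e-29), with adjusted p = 0.226 with an estimated correlation.

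Pigment, proliferation and sebaceous genes were higher in the same libraries. Of 14 melanocyte genes, 12 rose and 2, Kcnj13 and Met, fell (the same counts adjusted over the list alone, median 3.44). Dct, an enzyme of melanin synthesis, rose 43.3-fold to 386 ± 109 CPM (n = 3), and Mlana rose 76-fold. The list was called higher (adjusted p = 1.32e-06), with adjusted p = 0.275 with an estimated correlation. Of 20 cell cycle genes, 16 rose (16 higher and 1 lower adjusted over the list alone, median 2.02). Plk1, a mitotic kinase, rose 10.7-fold and Cdk1 rose 6.29-fold to 86.5 ± 13.7 CPM (list adjusted p = 2.38e-10, and adjusted p = 0.275 with an estimated correlation). Of 14 sebaceous gland genes, 9 rose (median 1.16), among them Elovl3, a fatty acid elongase, 4.54-fold (list adjusted p = 0.00557, and adjusted p = 0.502 with an estimated correlation).

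The interfollicular epidermis moved both ways. Of 12 basal keratinocyte genes, 9 fell and 1, Cdh3, rose (9 and 2 adjusted over the list alone, median -1.28). Col17a1, a hemidesmosomal collagen, went from 1343 ± 387 to 240.0 ± 55.9 CPM (n = 3, 5.6-fold lower), Lamb3 was 5.43-fold lower and Krt15 4.08-fold lower. The list was called lower (adjusted p = 0.00361), with adjusted p = 0.382 with an estimated correlation, and without control uninjured 3 the call was lost (median -0.96, adjusted p = 0.0636). Of 18 genes of wound-activated keratinocytes, 11 rose (13 adjusted over the list alone, median 4.39). S100a7a, an antimicrobial protein, rose 41.9-fold to 44.6 ± 15.1 CPM, Sprr2k rose 21.4-fold, and Krt17, which the hair follicle also expresses, rose 4.23-fold. That list was called higher (adjusted p = 1.82e-05, and adjusted p = 0.382 with an estimated correlation), and its median was 6.60 without control uninjured 3. Of 20 genes of differentiating keratinocytes, 4 rose and 7 fell (4 and 8 adjusted over the list alone, median -0.30, camera adjusted p = 0.729), with Dsg1a 4.33-fold and Flg2 4.37-fold lower.

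Dermal matrix, fat and muscle genes were higher in injured control skin. Of 24 matrix genes, 23 rose (23 adjusted over the list alone, median 3.07, adjusted p = 4.54e-13, and adjusted p = 0.313 with an estimated correlation). Eln, which encodes elastin, went from 12.3 ± 4.02 to 260.4 ± 82.3 CPM (n = 3, 21-fold), Fbn1 rose 12-fold and Col12a1 8.51-fold. Of 16 myofibroblast genes, 9 rose and 2, Cnn1 and Tgfbi, fell (median 1.24, adjusted p = 0.00904, and adjusted p = 0.474 with an estimated correlation). Tagln, an actin-binding protein, rose 2.87-fold and Adam12 12.6-fold. The fat list had 15 of 16 genes higher and Acsl1 lower (median 2.66, adjusted p = 4.23e-07, and adjusted p = 0.326 with an estimated correlation). Lpl, lipoprotein lipase, rose 12.1-fold to 392 ± 154 CPM. Of 18 skeletal muscle genes, 16 rose (median 2.70, adjusted p = 6.72e-05, and adjusted p = 0.474 with an estimated correlation), with Atp2a1, the calcium pump of fast muscle, at 186 ± 23.8 and 702 ± 429.7 CPM. Without the 2 uninjured control libraries of highest background, an alternative chosen after seeing the data, the myofibroblast call was lost (median 1.00, adjusted p = 0.097), as it was with the filter of 2 CPM in 3 samples (median 1.15, adjusted p = 0.0517). Without those libraries the sebaceous median was 0.71.

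Immune and vessel genes also moved. Of 16 macrophage genes, 13 rose (median 2.21, adjusted p = 1.78e-09, and adjusted p = 0.275 with an estimated correlation). C1qa, a subunit of complement C1q, rose 15.3-fold to 74.6 ± 13.3 CPM (n = 3), and Mrc1 rose 11.2-fold. Of 15 mast cell genes, 11 rose and Hpgds and Mrgprb2 fell (median 1.53, adjusted p = 0.000166, and adjusted p = 0.275 with an estimated correlation). The mast cell tryptase Tpsb2 rose 54.5-fold to 84.5 ± 20.8 CPM, and Kit, also a melanocyte gene, rose 3.63-fold. Of 20 cytokine genes, 10 rose and Il1a and Cxcl16 fell (median 1.08, adjusted p = 0.00361, and adjusted p = 0.382 with an estimated correlation), with Il1b 13.4-fold and Ccl8 6.11-fold higher. The cytokine median was 1.68 without control uninjured 3. Blood endothelium had 11 of 14 genes higher, with Cdh5 up 3.87-fold (median 1.01, adjusted p = 0.000322, and adjusted p = 0.447 with an estimated correlation). Lymphatic endothelium had 4 of 8 higher and 1 lower (median 1.09, adjusted p = 0.0199, and adjusted p = 0.382 with an estimated correlation), with Pdpn up 7.88-fold. Red blood cell genes were higher in 4 of 6 cases, with Hba-a1 up 4.63-fold (median 3.11, adjusted p = 0.000434, and adjusted p = 0.226 with an estimated correlation). The RAS and ERK output list had 8 of 18 genes higher and 1 lower, with Etv4 up 7.19-fold (median 0.74, adjusted p = 0.0087, and adjusted p = 0.282 with an estimated correlation). With the filter of 2 CPM in 3 samples, the calls of the lymphatic (median 0.99, adjusted p = 0.081) and the RAS and ERK output list (median 0.73, adjusted p = 0.0645) were lost. With the ribosomal RNA-like covariate, chosen after seeing the data, the lymphatic and cytokine medians were 0.69 and 0.52.

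Camera called no nerve list in this comparison, although single members passed. Of 17 myelin genes, 8 fell and 1 rose (the same adjusted over the list alone, median -0.99, camera adjusted p = 0.139, called lower by fry with adjusted p = 0.0123), with Mbp, myelin basic protein, going from 155 ± 10.2 to 39.5 ± 3.85 CPM (n = 3, 3.91-fold lower). Of 20 other Schwann lineage genes, 4 rose and 8 fell (median -0.08, adjusted p = 0.924), with the neuregulin receptor gene Erbb3 2.1-fold lower and Shh, which the hair follicle also expresses, 8.96-fold higher. Of 13 axon genes, 4 rose and 4 fell (4 and 5 adjusted over the list alone, median -1.97, mean -0.82, adjusted p = 0.729), with Tubb3, a neuronal tubulin, 26.3-fold higher and Scn10a, a sodium channel of sensory neurons, 26-fold lower. Scn10a stood at 4.61, 3.84 and 1.58 CPM in control uninjured libraries 1 to 3. Their receptor family background had the same order (0.282, 0.213 and 0.0792 CPM per kb), so background may hold part of its fall. Camera and fry gave the axon list an upward direction, against its median. The other lists without a call by camera were neutrophil (5 rose and 2 fell of 12, median 1.61, adjusted p = 0.0904), B and plasma cell (3 and 3 of 9, 0.42, adjusted p = 0.924) and interferon (3 and 1 of 18, or 0 and 1 adjusted over the list alone, 0.26, adjusted p = 0.275). Dendritic genes (0 and 2 of 14, or 0 and 1 adjusted over the list alone, 0.23, adjusted p = 0.729), T and natural killer genes (1 and 6 of 16, or 1 and 5 adjusted over the list alone, -0.54, adjusted p = 0.41, called lower by fry with adjusted p = 0.0219) and immediate early genes (3 and 5 of 16, -0.24, adjusted p = 0.924) had no call by camera either. The means of the dendritic (-0.08) and B and plasma cell lists (-0.84) were opposite in sign to their medians, and camera pointed up for the immediate early list.

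In all, edgeR called 13072 of 23635 genes between injured and uninjured control skin, 5393 higher and 7679 lower, and 14266 genes had unadjusted p under 0.05. The groups did not overlap for 14757 genes (62.4%, where chance gives 10%). By the naming rule, the largest falls were in Y-linked genes and in genes with few counts. Eif2s3y, Uty and Kdm5d, with 0 counts in injured control skin, were at least 1050-fold, 525-fold and 288-fold lower, and the Ddx3y ratio was 4120 (739 to 163000). Cntnap5a, Vmn1r13, Fsip2 and Vmn1r28 were at least 96.9-fold, 87.4-fold, 76.2-fold and 68.8-fold lower, with a higher receptor family background in the uninjured libraries. The sex-marker list had a median of -11.22, or -9.04 with genes at 0 counts placed at their bound. Among mitochondrial transcripts, mt-Nd6 was 1.76-fold higher and mt-Nd5 1.6-fold lower. With the ribosomal RNA-like covariate, chosen after seeing the data, mt-Nd5 was not called (log2 0.052, edgeR adjusted p = 0.892). Of the genes called, 41.3% were higher in edgeR, 33.4% in edgeR without a filter, and 29.8% in DESeq2, which was run on all genes with a count. The share was 48.6% with the filter of 2 CPM in 3 samples, 46.8% in the compared groups alone, and 45% after subtraction of background. Alternatives chosen after seeing the data gave 8423 genes with the ribosomal RNA-like share as a covariate and 6164 without control uninjured 1 and 2.

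**Figure D2:**
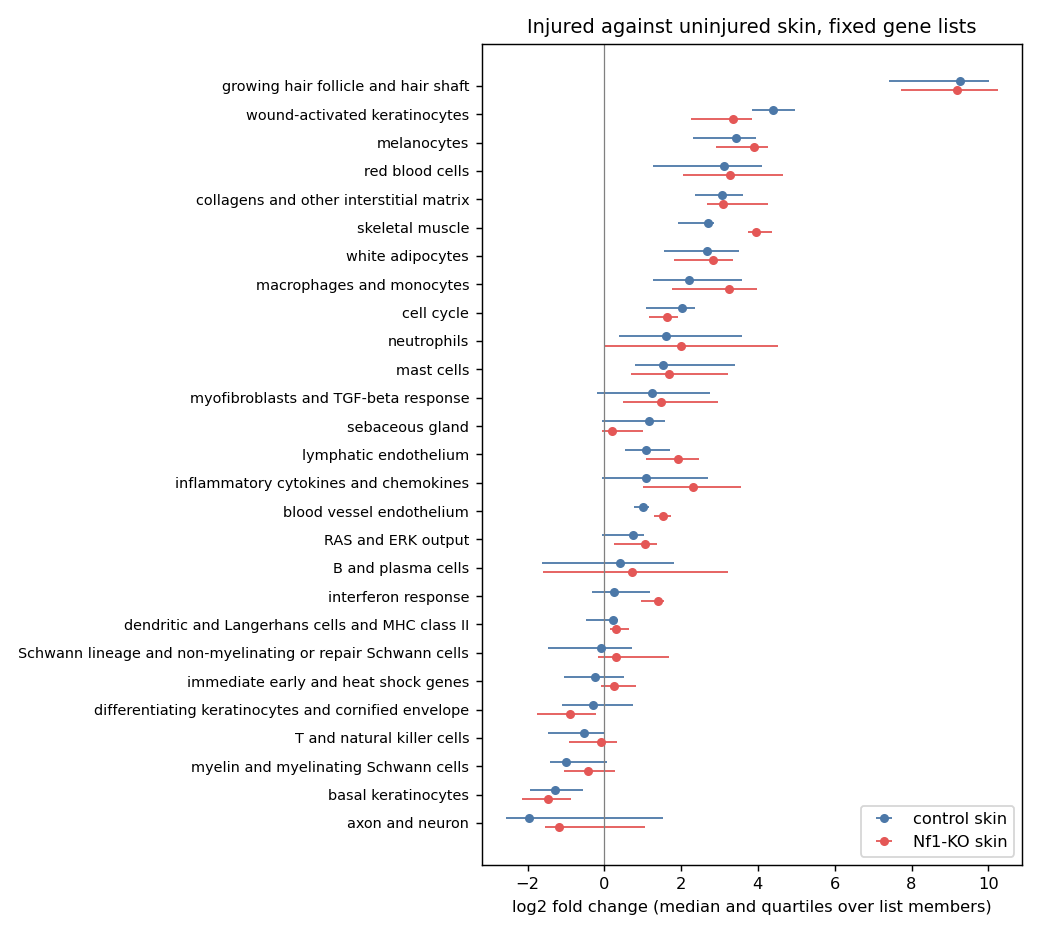
Log2 fold change of each gene list with injury in control and in Nf1-KO skin, with points for list medians and lines for quartiles. The hair follicle list has medians of 9.26 and 9.17, and the basal keratinocyte list has medians of -1.28 and -1.48.

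Injured Nf1-KO skin, compared with uninjured Nf1-KO skin, also had higher levels of hair follicle genes. All 23 hair follicle genes rose (23 adjusted over the list alone, as where no second count is given, median 9.17, adjusted p = 3.51e-34, and adjusted p = 0.169 with an estimated correlation). Krt31 rose 1649-fold, Krt34 2048-fold and Krt81 1984-fold, all keratins of the hair shaft, and Krtap14 reached 903 ± 566 CPM (n = 3, 3399-fold). All 16 macrophage genes rose (median 3.25, adjusted p = 5.7e-14, and adjusted p = 0.181 with an estimated correlation), with Ccr2, a chemokine receptor of monocytes, going from 3.69 ± 1.25 to 50.2 ± 28 CPM. Of 24 matrix genes, 23 rose (median 3.08, adjusted p = 7.08e-17, and adjusted p = 0.181 with an estimated correlation), with Fbn1 29.8-fold and Dcn, decorin, 7.71-fold higher. All 18 muscle genes rose (median 3.95, adjusted p = 4.98e-12, and adjusted p = 0.181 with an estimated correlation), with Atp2a1 going from 41.7 ± 29.3 to 597 ± 75.2 CPM (14.3-fold).

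Other lists were called in Nf1-KO skin as well. Melanocyte genes had 12 higher and 2 lower of 14 (median 3.89, adjusted p = 2.6e-08, and adjusted p = 0.181 with an estimated correlation), with Slc45a2 37.4-fold higher. Adipocyte genes had 13 higher and 1 lower of 16 (median 2.82, adjusted p = 2.83e-07, and adjusted p = 0.181 with an estimated correlation), with Lpl 17.3-fold higher. Cell cycle genes had 16 of 20 higher (median 1.63, adjusted p = 5.33e-09, and adjusted p = 0.181 with an estimated correlation), and red blood cell genes had 6 of 6 (median 3.27, adjusted p = 1.76e-05, and adjusted p = 0.169 with an estimated correlation). Blood endothelium had 13 of 14 higher (median 1.54, adjusted p = 2.6e-08, and adjusted p = 0.181 with an estimated correlation), with Kdr, a VEGF receptor, 4.62-fold higher. Lymphatic endothelium had 5 of 8 higher (7 adjusted over the list alone, median 1.92, adjusted p = 0.000221, and adjusted p = 0.181 with an estimated correlation). Cytokine genes had 14 higher and 2 lower of 20 (15 and 2 adjusted over the list alone, median 2.31, adjusted p = 2.65e-05, and adjusted p = 0.181 with an estimated correlation), with Ccl12 22.7-fold higher. Mast cell genes had 8 higher and 2 lower of 15 (9 and 2 adjusted over the list alone, median 1.70, adjusted p = 0.000272, and adjusted p = 0.181 with an estimated correlation). Myofibroblast genes had 11 higher and 2 lower of 16 (12 and 2 adjusted over the list alone, median 1.49, adjusted p = 0.000522, and adjusted p = 0.302 with an estimated correlation). RAS and ERK output genes had 10 higher and 1 lower of 18 (median 1.05, adjusted p = 0.000887, and adjusted p = 0.181 with an estimated correlation), with Dusp6, a phosphatase of ERK, 3.13-fold higher.

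Keratinocyte lists went in opposite directions. Basal genes had 9 lower and 1 higher of 12 (median -1.48, adjusted p = 3.11e-06, and adjusted p = 0.181 with an estimated correlation), with Krt15 going from 7684 ± 438 to 916 ± 216 CPM (n = 3, 8.39-fold lower). Differentiation genes had 9 lower and 1 higher of 20 (11 and 1 adjusted over the list alone, median -0.90, adjusted p = 0.000424, and adjusted p = 0.312 with an estimated correlation), with Krt77 5.96-fold lower. Wound-activated genes had 5 of 18 higher (median 3.34, adjusted p = 0.000347, and adjusted p = 0.35 with an estimated correlation), with S100a7a 89.7-fold higher. Without Nf1-KO uninjured 3 the medians of the differentiation and wound-activated lists were -0.52 and 5.89. Neutrophil genes had 6 of 12 higher (median 2.00, adjusted p = 0.0435, and adjusted p = 0.508 with an estimated correlation). Interferon genes had 10 of 18 higher (median 1.40, adjusted p = 0.00482, adjusted p = 0.557 with an estimated correlation, and adjusted p = 0.0773 with fry). Without Nf1-KO injured 3, the neutrophil (median 1.24, adjusted p = 0.0974) and interferon (median 0.57, adjusted p = 0.0576) calls were lost. The neutrophil median was 3.52 without Nf1-KO uninjured 3 and 3.41 with the filter of 2 CPM in 3 samples. Of alternatives chosen after seeing the data, the ribosomal RNA-like covariate lost the neutrophil (median 1.36, adjusted p = 0.222) and interferon calls (median 0.92, adjusted p = 0.0739). Leaving out Nf1-KO uninjured 1 and 2 lost the neutrophil call (median 1.57, adjusted p = 0.0617) and gave medians of -1.46 for differentiation, 1.81 for wound-activated, 0.93 for interferon and 0.59 for RAS and ERK output genes.

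Nerve lists had no call in Nf1-KO skin by camera or fry. Myelin genes had 5 lower and 1 higher of 17 (median -0.43, adjusted p = 0.354), with Mbp 3.26-fold lower, and other Schwann lineage genes had 6 higher and 3 lower of 20 (7 and 3 adjusted over the list alone, median 0.31, adjusted p = 0.315). Axon genes had 3 higher and 2 lower of 13 (median -1.17, mean -0.18, camera direction up, adjusted p = 0.627). The sebaceous (median 0.21, adjusted p = 0.378), B and plasma cell (0.73, adjusted p = 0.399), dendritic (0.30, adjusted p = 0.498), T and natural killer (-0.09, adjusted p = 0.6) and immediate early lists (0.26, adjusted p = 0.895) also had no call. Single immune genes passed, among them Cd207 of Langerhans cells, 6.63-fold lower, and Igkc, an immunoglobulin light chain gene, with a ratio of 105 (35.6 to 509) from 3 counts in uninjured skin. The ratio of Retnlg, a neutrophil gene, was 103 (28.2 to 854) higher in injured skin.

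In all, edgeR called 8851 genes with injury in Nf1-KO skin, 4506 higher and 4345 lower, and 11364 had unadjusted p under 0.05. The groups did not overlap for 12190 genes (51.6%, where chance gives 10%). Ddx3y, Eif2s3y, Uty and Kdm5d, with 0 counts in injured skin, were at least 1140-fold, 784-fold, 295-fold and 228-fold lower. The sex-marker median was -10.95, or -8.20 with such genes at their bound. Defb8, with 0 counts in injured Nf1-KO skin, was at least 131-fold lower, and the ratios for Best2 and Itln1 were 407 (72.6 to 16100) and 63.9 (17.2 to 535). Under median-of-ratios scaling the median log2 fold change of all genes moved from -0.09 to -0.20. Of the genes called, 50.9% were higher in edgeR, 45.4% in edgeR without a filter and 39.7% in DESeq2, which had no such filter either. The share was 62.6% without Nf1-KO injured 1 (3857 higher and 2307 lower), 56.1% without Nf1-KO uninjured 3 and 40.5% without Nf1-KO injured 3. The count was 5647 without Nf1-KO uninjured 2, and 2062 without Nf1-KO uninjured 1 and 2, the latter chosen after seeing the data.

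Both injury responses resembled each other across genes. Their log2 fold changes correlated with Pearson's r = 0.853 and Spearman's rho = 0.895 over 23635 genes, and the sign was the same for 87% of them. In both genotypes, 3730 genes were higher and 3824 lower, where independent lists would share 1028 and 1412, and 3 genes moved in opposite directions. Leaving out single libraries gave correlations of 0.811 to 0.896. The comparisons share no library, but male and female markers, hair follicle genes and background moved with injury in both.

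Uninjured Nf1-KO skin differed from uninjured control skin in few genes. Glul (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723), which encodes glutamine synthetase, was at 141 ± 40.5 CPM in Nf1-KO and 39 ± 7.09 in control skin (n = 3, 3.62-fold, log2 1.86 with SE 0.23, adjusted p = 0.00718). Nuak1, a kinase related to AMPK (chromosome 10, 84370905 to 84440597), was 2.79-fold higher (37.5 ± 10.6 against 13.4 ± 0.652 CPM, adjusted p = 0.0485). Srp9, a subunit of the signal recognition particle (chromosome 1, 182124737 to 182132407), was 2.02-fold higher (50.4 ± 4.06 against 25 ± 3.21 CPM, adjusted p = 0.0485). Slfn9, of the Schlafen family (chromosome 11, 82978390 to 82991830), was 3.63-fold lower (3.67 ± 0.285 against 13.3 ± 1.94 CPM, adjusted p = 0.0485). Teddm2 (chromosome 1, 153849542 to 153900228) and Mir8114 (chromosome 1, 153899926 to 153900036), which overlap the start of Glul, were 2.73-fold and 3.24-fold higher (adjusted p = 0.0485 each). Gm8210 (chromosome 1, 43189156 to 43189638), named although its symbol is outside the naming rule, had 86 counts against 2, a ratio of 45.4 (12.2 to 381, adjusted p = 0.0175). In injured skin, Glul was at 103 ± 12.6 in Nf1-KO and 106 ± 15.8 CPM in control libraries.

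These 7 genes, 6 higher and 1 lower, were all that edgeR called, and 1971 genes had unadjusted p under 0.05. The groups did not overlap for 3506 genes (14.8%, where chance gives 10%), among them all 7. The other tools and settings gave 60 genes with DESeq2, 2 with voom, 4 with median-of-ratios scaling, 219 without a filter, 2 with a filter of 2 CPM in 3 samples, 27 when the compared groups were fitted alone, and 1 with a replicate block. Glul was called in each of these with 4 or fewer genes. Without control uninjured 1 the count was 0, and without control uninjured 2 it was 1, Glul. Without control uninjured 3 it was 1, Fkbp5 (log2 2.70, adjusted p = 0.00402, named after its value was seen). Without Nf1-KO uninjured 1 and 2 in turn it was 4 and 2. Alternatives chosen after seeing the data gave 1 gene, Glul, with the ribosomal RNA-like covariate, and 6 genes without control uninjured 1 and 2, of which 0 were among the 7. In that fit, with 1 control library left, the 7 calls were lost while the fold changes of Glul (log2 2.11) and Slfn9 (log2 -2.11) were as large as before.

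**Figure D3:**
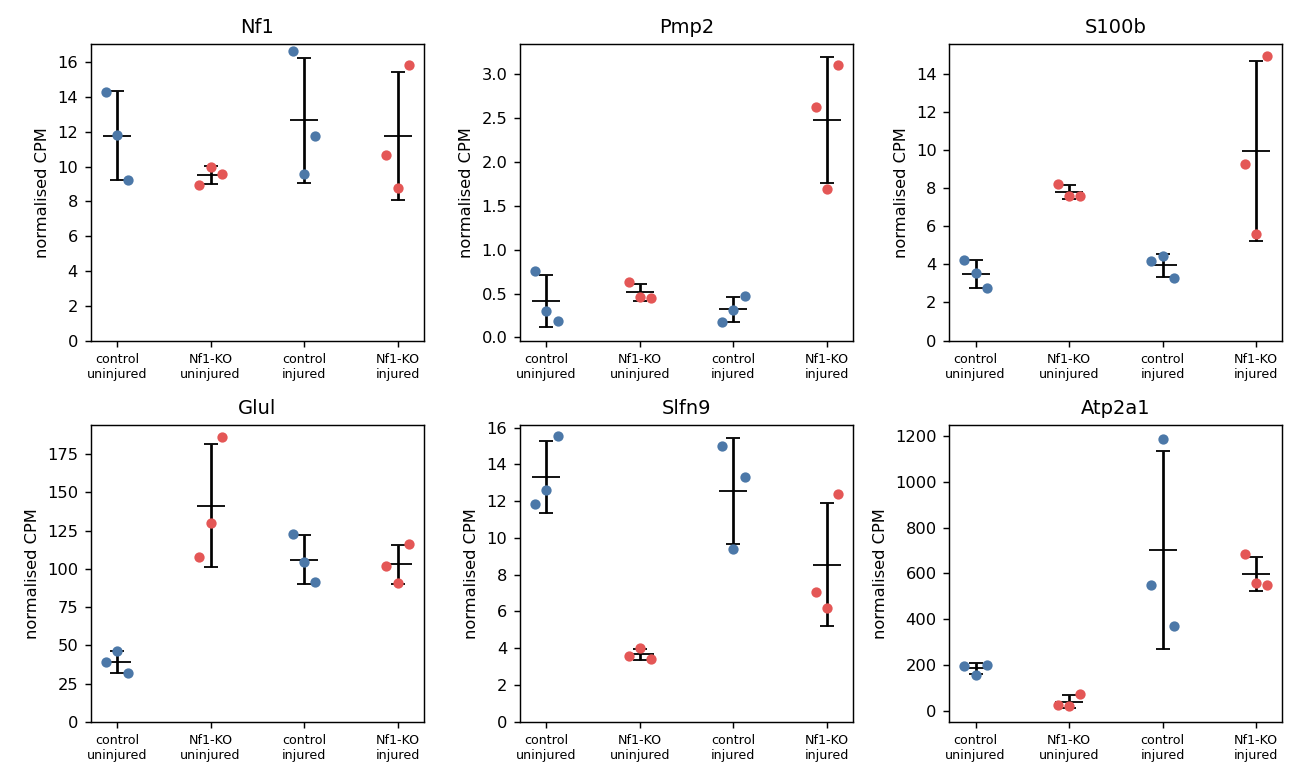
Normalised CPM of Nf1, Pmp2, S100b, Glul, Slfn9 and Atp2a1 in each library, by group, with points for libraries and bars for mean ± SD (n = 3). Glul is at 39 ± 7.09 in control uninjured and 141 ± 40.5 in Nf1-KO uninjured skin, and Pmp2 is at 2.47 ± 0.715 in Nf1-KO injured and 0.321 ± 0.145 in control injured skin.

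Among cell type lists in uninjured skin, muscle genes were lower and sebaceous genes higher with Nf1-KO. No list member passed over all genes. Of 18 muscle genes, 0 had a positive log2 fold change (median -1.75) and 8 were lower adjusted over the list alone. Atp2a1 was at 41.7 ± 29.3 CPM in Nf1-KO and 186 ± 23.8 in control skin (n = 3, log2 -2.16, adjusted p = 0.348). The muscle list was called lower (adjusted p = 4.94e-23, and adjusted p = 0.494 with an estimated correlation), with a median of -2.73 without Nf1-KO uninjured 3. Of 14 sebaceous genes, 13 had a positive log2 fold change (median 0.79) and 3 were higher adjusted over the list alone (list adjusted p = 3.11e-09, and adjusted p = 0.494 with an estimated correlation). Dgat2l6, an acyltransferase of the gland, had 12.1 ± 4.2 against 3.79 ± 1.8 CPM (adjusted p = 0.256). The myelin list was called higher (median 0.22, 1 of 17 adjusted over the list alone, list adjusted p = 0.0315, and adjusted p = 0.853 with an estimated correlation). The myelin median was -0.03 without Nf1-KO uninjured 1, 0.13 without control uninjured 2 and 0.40 without Nf1-KO uninjured 3, and the call was lost in 3 of 6 such fits, among them those without control uninjured 3 (median 0.179, adjusted p = 0.0617) and Nf1-KO uninjured 2 (median 0.186, adjusted p = 0.0699). It was also lost with the filter of 2 CPM in 3 samples (median 0.17, adjusted p = 0.104) and after subtraction of background, chosen after seeing the data (median 0.18, adjusted p = 0.0586).

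Immune and vessel lists were called in uninjured skin with smaller shifts. The dendritic list was higher (median 0.54, 5 of 14 adjusted over the list alone, adjusted p = 0.000393, and adjusted p = 0.801 with an estimated correlation), with H2-DMa, an MHC class II chaperone, at 67 ± 12.5 against 40.6 ± 2.39 CPM (n = 3, adjusted p = 0.51). The T and natural killer list was lower (median -0.51, 1 of 16 with a positive log2 fold change, 0 adjusted over the list alone, adjusted p = 0.00131, and adjusted p = 0.494 with an estimated correlation). Its median was -0.28 without control uninjured 1, -0.33 without Nf1-KO uninjured 2 and -0.29 without Nf1-KO uninjured 3, where the call was lost (adjusted p = 0.0605). The endothelial list was lower (median -0.39, 1 of 14 adjusted over the list alone, adjusted p = 0.000648, and adjusted p = 0.853 with an estimated correlation), with a median of -0.63 without Nf1-KO uninjured 1, -0.24 without Nf1-KO uninjured 3, and -0.08 without control uninjured 1, where the call was lost (adjusted p = 0.0629). The cytokine list was lower (median -0.33, 1 of 20 adjusted over the list alone, adjusted p = 0.042, and adjusted p = 0.853 with an estimated correlation), a call lost without control uninjured 3 (median -0.216, adjusted p = 0.537), Nf1-KO uninjured 1 (median -0.479, adjusted p = 0.0596) and Nf1-KO uninjured 2 (median -0.488, adjusted p = 0.189). The cytokine call was also lost with the filter of 2 CPM in 3 samples (median -0.283, adjusted p = 0.18) and after subtraction of background (median -0.359, adjusted p = 0.123), and its median was -0.57 with the ribosomal RNA-like covariate. The cell cycle list was higher (median 0.18, 0 of 20 adjusted over the list alone, adjusted p = 0.00918, and adjusted p = 0.853 with an estimated correlation). That call was lost without control uninjured 1 (median 0.177, adjusted p = 0.0745) and Nf1-KO uninjured 3 (median 0.03, adjusted p = 0.594), and the median was 0.43 without control uninjured 3. The RAS and ERK output list was not called (median -0.04, mean 0.04, adjusted p = 0.961). Fry called 0 of the 27 lists. Without control uninjured 1 and 2, chosen after seeing the data, all calls but those of the muscle and cytokine lists were lost in a fit with 1 control library (adjusted p from 0.0755 to 0.917). The medians were then 0.275 for myelin, 0.456 for dendritic, 0.499 for sebaceous, -0.233 for T and natural killer, -0.095 for endothelial and 0.122 for cell cycle genes, so that the myelin shift did not shrink.

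Injured Nf1-KO skin, compared with injured control skin, had higher levels of Schwann cell genes as lists, while no single gene passed in edgeR. Of 17 myelin genes, 16 had a positive log2 fold change (median 0.48) and 4 were higher adjusted over the list alone (list adjusted p = 1.73e-05, and adjusted p = 0.451 with an estimated correlation). Pmp2, a lipid-binding protein of myelin, was at 2.47 ± 0.715 in Nf1-KO and 0.321 ± 0.145 CPM in control skin (n = 3, log2 2.88, adjusted p = 0.346). Of 20 other Schwann lineage genes, 17 had a positive log2 fold change (median 0.92) and 7 were higher adjusted over the list alone (list adjusted p = 0.000181, and adjusted p = 0.629 with an estimated correlation). S100b, a calcium-binding protein of Schwann cells (chromosome 10, 76253853 to 76261159), was at 9.95 ± 4.73 against 3.96 ± 0.608 CPM (log2 1.32, adjusted p = 0.348). Sox10, a Schwann lineage transcription factor named after its values were seen, was at 25.7 ± 17.6 against 10.0 ± 3.29 CPM (adjusted p = 0.355). The myelin median was 0.26 without Nf1-KO injured 2, and the Schwann lineage median was 0.33 without Nf1-KO injured 3, and both lists kept their calls. Nf1-KO injured 3 and 2 were also the injured libraries of highest background, and without both, chosen after seeing the data, the medians were 0.15 and 0.39.

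Macrophage, dendritic and interferon lists were higher and keratinocyte lists lower in the same comparison. Of 16 macrophage genes, 15 had a positive log2 fold change (median 0.94, 1 adjusted over the list alone, adjusted p = 1.71e-06, and adjusted p = 0.568 with an estimated correlation), with Ccr2 at 50.2 ± 28 against 20.4 ± 3.71 CPM (n = 3, adjusted p = 0.355). Of 14 dendritic genes, 13 were positive (median 0.56, 4 adjusted over the list alone, adjusted p = 6.7e-05, and adjusted p = 0.568 with an estimated correlation), with Cd209a at 20 ± 1.11 against 10.1 ± 1.59 CPM (adjusted p = 0.355). All 18 interferon genes were positive (median 0.86, 0 adjusted over the list alone, adjusted p = 0.00608, and adjusted p = 0.817 with an estimated correlation). Without Nf1-KO injured 3 the medians were 0.42 for macrophage, 0.17 for dendritic and 0.01 for interferon genes, and the interferon call was lost (adjusted p = 0.656), as it was without control injured 2 (median 0.599, adjusted p = 0.145). Of 20 genes of differentiating keratinocytes, 2 were positive (median -0.68) and 4 were lower adjusted over the list alone (list adjusted p = 5.97e-17, and adjusted p = 0.23 with an estimated correlation). Krtdap, a protein of differentiating keratinocytes, was at 2855 ± 83.3 against 5020.4 ± 253 CPM (log2 -0.81, adjusted p = 0.355). Basal (median -0.33, 0 adjusted over the list alone, adjusted p = 1.71e-06, and adjusted p = 0.451 with an estimated correlation) and wound-activated lists (median -0.70, 0 adjusted over the list alone, adjusted p = 0.000102, and adjusted p = 0.629 with an estimated correlation) were lower too. The basal median was -0.21 without Nf1-KO injured 1 and -0.61 without Nf1-KO injured 2, and the wound-activated median was -0.43 without control injured 1.

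The remaining called lists of injured skin had medians from -0.28 to -0.10. They were adipocyte (median -0.28, 0 of 16 adjusted over the list alone, adjusted p = 0.000693, and adjusted p = 0.629 with an estimated correlation), T and natural killer (-0.10, 1 of 16 higher adjusted over the list alone, adjusted p = 0.0181, and adjusted p = 0.604 with an estimated correlation) and mast cell genes (-0.28, 0 of 15 adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.629 with an estimated correlation). The adipocyte call was lost without control injured 2 (median -0.03, adjusted p = 0.15), and the median was -0.57 without control injured 1 and -0.50 without Nf1-KO injured 2. The T and natural killer call was lost without control injured 1 (median 0.00, adjusted p = 0.0819) and Nf1-KO injured 2 (median -0.14, adjusted p = 0.129), and its median ran from -0.378 to 0.0 over the fits with 1 library left out, and was -0.349 with the filter of 2 CPM in 3 samples. The mast cell call was lost without control injured 2 or 3 or Nf1-KO injured 1 or 2 (medians -0.01, -0.10, -0.13 and -0.18), and its median was -0.52 without Nf1-KO injured 3. It was also lost with median-of-ratios scaling (median -0.376, adjusted p = 0.0591), with the filter of 2 CPM in 3 samples (median -0.347, adjusted p = 0.108) and after subtraction of background (median -0.358, adjusted p = 0.079), where the shift was no smaller. Without Nf1-KO injured 2 and 3, chosen after seeing the data, the calls of wound-activated (median -0.55, adjusted p = 0.178), adipocyte (-0.40, adjusted p = 0.148), T and natural killer (-0.37, adjusted p = 0.182) and interferon genes (-0.17, adjusted p = 0.768) were lost. Hair follicle genes were positive in 23 of 23 cases (median 0.32, adjusted p = 0.38), and the RAS and ERK output (median 0.12, adjusted p = 0.717) and axon lists (median 0.60, adjusted p = 0.406) were not called. Fry called 0 of the 27 lists.

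In injured skin edgeR called 0 genes between genotypes, with 2532 genes at unadjusted p under 0.05, and the groups did not overlap for 2138 genes (9%, where chance gives 10%). DESeq2 called 124 genes, voom 1 (AA465934, log2 5.56, adjusted p = 0.0162, named after its value was seen) and the fit without a filter 410. The count was 57 without Nf1-KO injured 1, 89 without Nf1-KO injured 2, 1 without Nf1-KO injured 3 and 2 without control injured 1. Of alternatives chosen after seeing the data, leaving out Nf1-KO injured 2 and 3 gave 7 genes. The ribosomal RNA-like covariate gave 3, namely Brinp3 (log2 3.82, adjusted p = 0.0248), AA465934 (4.93, adjusted p = 0.00843) and 2010109I03Rik (-1.06, adjusted p = 0.034).

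**Figure D4:**
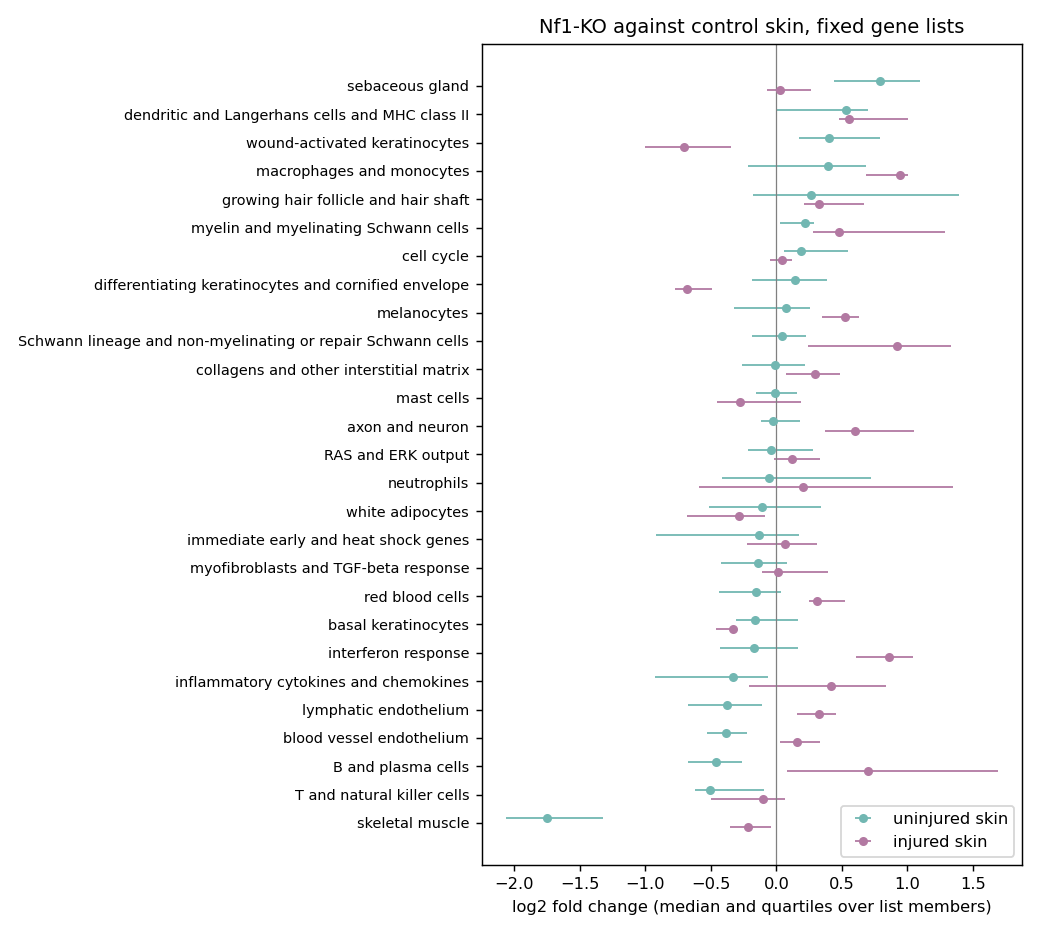
Log2 fold change of each gene list between Nf1-KO and control in uninjured and in injured skin, with points for list medians and lines for quartiles. In injured skin the medians are 0.48 for myelin and -0.68 for differentiating keratinocytes, and in uninjured skin the muscle median is -1.75.

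The difference between both injury responses was tested as an interaction, and edgeR called 0 genes, with 2541 at unadjusted p under 0.05, 37 called by DESeq2, 0 by voom and 236 without a filter. The smallest p belonged to 10 genes, none of which passed. Zbtb16, a zinc finger transcription factor induced by glucocorticoids (chromosome 9, 48654297 to 48836222), was at 44.1 ± 10.7 and 105 ± 8.25 CPM in uninjured control and Nf1-KO skin, and at 17 ± 6.38 and 6.65 ± 2.37 in injured skin (n = 3, log2 -2.61, adjusted p = 0.0984). Glul (log2 -1.90) and Brinp3 (log2 4.64, chromosome 1, 146494760 to 146902472) had the same adjusted p of 0.0984. Brinp3 was at 4.67 ± 2.23 and 3.18 ± 1.03 CPM in uninjured control and Nf1-KO skin and at 0.363 ± 0.14 and 6.3 ± 3.38 in injured skin. In control uninjured libraries 1 to 3 it was at 6.87, 4.76 and 2.40 CPM, the order of their receptor family background. Its uninjured level may thus be background in part. Its 8.33 CPM in Nf1-KO injured 1, with a background of 0.00156 CPM per kb, did not follow background. The others were Plscr4 (log2 2.57), Ifi202b (-2.90), Cbr3 (-1.58), Sult5a1 (-1.62), Dnase1l3 (-1.83), Gzmc (-2.85) and Best2, for which 1 count in injured Nf1-KO skin leaves no usable fold change, with adjusted p from 0.172 to 0.267. The count was 3 without control uninjured 3 (Fkbp5, Ifi202b and Zbtb16), 2 without Nf1-KO injured 2 or 3, and 1 without Nf1-KO uninjured 1, control injured 1 or control injured 3. Among alternatives chosen after seeing the data, the ribosomal RNA-like covariate gave 2 genes, Zbtb16 (adjusted p = 0.0135) and Brinp3 (adjusted p = 0.0244), and leaving out control uninjured 1 and 2 gave 2.

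Averaged over both skin states, a contrast added after seeing the data, 16 of 17 myelin genes had a positive log2 fold change with Nf1-KO (median 0.37, list adjusted p = 4.89e-06, and adjusted p = 0.297 with an estimated correlation). With 1 library left out the myelin median ran from 0.196, without Nf1-KO uninjured 1, to 0.48, and the call was kept in all 12 fits. With the ribosomal RNA-like covariate it was 0.602. In edgeR 0 genes were called, 2213 had unadjusted p under 0.05, and the counts were 58 with DESeq2, 1 with voom and 181 without a filter. The count was 44 without Nf1-KO injured 2, 6 without Nf1-KO injured 3, 3 without Nf1-KO uninjured 3 or control injured 1, 2 without Nf1-KO uninjured 2, and 1 without control injured 2 or 3. The Nf1-KO log2 fold changes of both skin states correlated at Pearson's r = -0.191 and Spearman's rho = -0.164 across genes.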

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

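The tests of genomic DNA, of strain DNA near Nf1 and of other splits of the samples were set down before their results were seen, and the tests of subtraction, sex, keratinocyte share, nerve and overlapping genes were chosen only after the result was seen.

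The response to injury of 8 gene lists differed between genotypes by camera on the interaction, where the log2 fold change is that of Nf1-KO minus control. Muscle (median 1.504, 18 of 18 genes positive, adjusted p = 2.06e-08), endothelial (0.513, 14 of 14, adjusted p = 0.0115) and interferon genes (1.128, 17 of 18, adjusted p = 0.0151) were on the higher side. Differentiating (-0.921, 5 of 20 positive, adjusted p = 5.64e-09), basal (-0.131, 4 of 12, adjusted p = 0.0115) and wound-activated keratinocyte genes (-1.261, 2 of 18, adjusted p = 0.0115) were on the lower side. Sebaceous (-0.783, 2 of 14 positive, adjusted p = 2.03e-05) and cell cycle genes (-0.232, 5 of 20, adjusted p = 0.0115) were lower too. Muscle and sebaceous lists differed between genotypes in uninjured skin (medians -1.752 and 0.789), and neither was called in injured skin. Each of the 8 lists had adjusted p = 0.831 with an estimated correlation, and fry gave adjusted p from 0.568 to 0.733. With 1 library left out, the muscle (median 1.112 to 2.597), differentiating (-1.103 to -0.44) and sebaceous calls (-1.183 to -0.408) were kept in all 12 fits. The endothelial (0.139 to 0.694) and interferon calls (0.284 to 1.47) were each lost in 4 of 12, both among them without Nf1-KO injured 3 (medians 0.139 and 0.284, adjusted p = 0.229 and 0.503). The wound-activated (-3.216 to 1.297) and cell cycle calls (-0.492 to 0.036) were lost in 3 and the basal call (-0.498 to -0.041) in 2. The wound-activated call was also lost with the filter of 2 CPM in 3 samples (median -1.283, adjusted p = 0.0605) and after subtraction of background (median -1.354, adjusted p = 0.0553), where the shift was no smaller, and with the ribosomal RNA-like covariate (median -0.707, adjusted p = 0.108). Without the 2 highest-background libraries the endothelial (median 0.285, adjusted p = 0.129), cell cycle (-0.06, adjusted p = 0.527), wound-activated (-0.04, adjusted p = 0.836) and basal calls (0.322, adjusted p = 0.93) were lost, in a fit with 1 control uninjured library. Of 40 splits of the 12 libraries, the real one included, 30 called at least as many lists (real 8, highest other 18), so chance cannot be excluded for these calls.

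Genes that fell with injury moved together with sex markers and with the background over silent genes. After subtraction of background, 6138 of the 7679 lower genes in control skin (79.9%) were still called lower. This argues against background at each library's mean density as the whole cause of the falls. Genes with a background above that density would keep part of it, so for them the subtraction cannot decide. The source of the background itself was tested through the X chromosome, on the premise that the uninjured libraries are male and the injured ones female. In silent genes (274 on the X, 4645 on autosomes) the ratio of X to autosome counts relative to Nf1-KO injured 3 was 0.57 (95% bootstrap interval 0.501 to 0.662) in uninjured libraries, and 1.038 (0.833 to 1.279) in Nf1-KO injured 2, consistent with genomic DNA. Sex and injury cannot be told apart, because 0 libraries carry markers of the other sex within their skin state, and the injury itself and the hair cycle stay open as untested explanations.

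Schwann and myelin lists were higher in injured Nf1-KO skin. After subtraction of background, the medians went from 0.48 to 0.352 for myelin and from 0.92 to 0.73 for the Schwann lineage. This argues against background at each library's mean density as the whole cause. However, without Nf1-KO injured 2 and 3 the medians were 0.15 and 0.39. A lower share of keratinocytes would raise markers of all other cell types alike. The upper quartile of the adipocyte list, at -0.09, lay below the lower quartile of the Schwann list, at 0.24. However, the adipocyte call was lost without control injured 2. Macrophage (median 0.945) and dendritic lists (0.556) were called higher, and mast cell (-0.281) and T and natural killer lists (-0.103) lower. The keratinocyte lists were lower as well, so the adipocyte list alone cannot decide this question. More nerve in the sampled skin cannot be told apart from a change in Schwann cells, because the axon median was 0.598 with adjusted p = 0.406. A change in Schwann cells with genotype may also account for the pattern, as a hypothesis from the same data.

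Few genes were called between genotypes in uninjured skin, and several of them lie close together. Glul and Teddm2 share 285 bases and Mir8114 overlaps them by 93 and 111, and the log2 fold changes of Glul and Teddm2 differ by 0.41 (combined SE 0.33), so the 3 calls may reflect 1 transcript counted under 3 genes. Strain DNA around Nf1, carried along with the targeted allele, cannot be told apart from chance. Genes within 10 Mb of Nf1 had unadjusted p under 0.05 in 42 of 421 cases, against 1929 of 23214 elsewhere, an odds ratio of 1.22 (0.86 to 1.69, Fisher's exact p = 0.213). In injured skin it was 0.95 (0.67 to 1.3, Fisher's exact p = 0.811), which argues against a share raised by 1.5 times in both skin states, but not against strain DNA behind a single gene of the region, such as Slfn9. Over the whole of chromosome 11 the odds ratio, chosen after the data were seen, was 1.25 (1.05 to 1.47, adjusted p = 0.0448) in uninjured and 0.73 (0.61 to 0.87, adjusted p = 0.00223) in injured skin, with higher values on other chromosomes. The genotype itself stays open as an explanation.

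The libraries of each comparison between groups of 3 can be split in 10 ways, which are too few for a share under 0.05. For genes called, the real value and the highest other were 13072 and 0 for injury in control skin, 8851 and 0 for injury in Nf1-KO skin, 7 and 1 for Nf1-KO in uninjured skin, and 0 and 558 for Nf1-KO in injured skin. As many genes as the real split were called by 1, 1, 1 and 10 of the splits, the real one included, where the 10 follows from a real count of 0. The split of injured libraries that called 558 genes set control 1, Nf1-KO 1 and Nf1-KO 3, the injured libraries with the highest ribosomal RNA-like share, against the rest, which points to a structure of the samples other than genotype. For lists called, the real value and the highest other were 17 and 17, 19 and 19, 8 and 22, and 11 and 16 in the same order. As many lists were called by 2, 4, 8 and 6 of the splits, and the medians of the other splits were 13, 17, 9 and 11. Chance cannot be excluded for the lists called between genotypes within a skin state. For the interaction and for the contrast over both skin states, the latter added after the data were seen, 40 splits of all 12 libraries were used, the real one included. The real count of genes was 0 in both (highest other 47 and 79), so all 40 splits reach it by construction and the count of splits says nothing about chance. At least the real 14 lists of the contrast over both skin states were called by 7 of the 40 splits (highest other 16), and chance cannot be excluded for them.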

How the results depend on the processing

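Subtraction of background, removal of the highest-background libraries, the ribosomal RNA-like covariate and the contrast over both skin states were chosen only after the data were seen, and the other alternatives were planned. Of gene results under all alternatives, 3234 kept direction and side of the threshold, 166 lost and 37 gained a call, and 2 reversed. Of list results, 2247 kept both, 219 lost and 113 gained a call, and 13 reversed. Counts of genes and lists and the agreement stayed in 162 cases and moved in 61. Except where construction is named, the cause was not tested. Injury counts were 13072 in control skin (10915 to 14006 with 1 library left out, 8423 with the covariate, 6164 without the 2 highest-background libraries) and 8851 in Nf1-KO skin (5647 to 10020, and 2062 without those libraries). In those fits fewer samples remain, and 1 library stands for an arm and is assumed to vary like the other groups. The 7 genes of Nf1-KO in uninjured skin became 4 with median-of-ratios scaling, 219 without a filter, 2 with 2 CPM in 3 samples, 27 in the compared groups alone, 2 with voom, 60 with DESeq2, 1 with the covariate and 0 to 6 with 1 library left out. The 0 genes of injured skin became 410 without a filter, 1 with voom, 124 with DESeq2, 3 with the covariate, 7 without the 2 highest-background libraries and 0 to 89 with 1 library left out. The 0 genes of the interaction became 236 without a filter, 37 with DESeq2, 2 with the covariate, 2 without those libraries and 0 to 3 with 1 library left out. Over both skin states, 0 became 181 without a filter, 1 with voom, 58 with DESeq2, 1 with the covariate, 4 without those libraries and 0 to 44 with 1 library left out. The replicate block gave 1 gene for Nf1-KO in uninjured skin and changed no other count by over 1.5 times, and the pairing check showed that replicate numbers do not pair the samples. Lists called fell from 17, 19, 8, 11, 8 and 14 to 0 in all 6 contrasts with an estimated correlation. With fry they fell to 0 in the 4 contrasts that involve genotype. The covariate gave 13 lists in uninjured skin. With 1 library left out, lists called ranged from 16 to 17, 17 to 20, 8 to 12, 10 to 14, 5 to 14 and 10 to 17. Agreement of injury responses was 0.853 (0.811 to 0.896).

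Reversals were in these results. For Nf1-KO in uninjured skin, the matrix median was -0.539 to 0.381 with 1 library left out and the wound-activated median -2.171 to 2.837. Without the 2 highest-background libraries the wound-activated median was -0.69, and the cell cycle list had a median of 0.122 (0.029 to 0.428 with 1 library left out) with the test pointing down. In injured skin the ranges with 1 library left out were -0.203 to 0.589 for matrix, -0.563 to 0.619 for muscle, -0.265 to 0.301 for endothelium, 0.008 to 1.127 for interferon and -0.285 to 0.149 for immediate early genes. Without the 2 highest-background libraries, interferon was -0.169 and immediate early genes 0.3. For the interaction, basal keratinocyte genes were 0.322 without those libraries (-0.498 to -0.041 with 1 left out) and wound-activated genes -3.216 to 1.297. Over both skin states wound-activated genes were -1.355 to 0.926. With injury, mt-Nd5 was 0.052 in control skin with the covariate (-0.969 to -0.451 with 1 left out) and Trdc was 0.559 in Nf1-KO skin without those libraries (-2.466 to -1.314). Calls were made at 8817013 to 16809687 counts per library. Genes under the count minimum of 10 were tested only without a filter and by DESeq2, so the other counts leave them out. Without a filter, 19318 genes were called for injury in control skin, 11886 of them among the 13072 of the main fit.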

Other observations

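The contrast over both skin states, the comparison of chromosomes and the test on distal chromosome 1 were chosen only after the data were seen.

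Averaged over uninjured and injured skin, Nf1-KO libraries had higher levels of antigen-presenting cell genes and lower levels of T cell genes. Of 14 dendritic and MHC class II genes, 13 had a positive log2 fold change (median 0.60, adjusted p = 1.37e-07, and adjusted p = 0.297 with an estimated correlation). Of 16 macrophage genes, 15 were positive (median 0.52, adjusted p = 1.11e-05, and adjusted p = 0.435 with an estimated correlation). The macrophage list was called in injured skin (median 0.945) but not in uninjured skin. Without Nf1-KO injured 3 the dendritic and macrophage medians were 0.351 and 0.321, and both calls were kept in all 12 fits with 1 library left out. Of 16 T and natural killer genes, 3 were positive (median -0.27, adjusted p = 1.92e-05, and adjusted p = 0.297 with an estimated correlation), and Cd3e, a chain of the T cell receptor complex, was at 15.3 ± 6.96 against 23.5 ± 1.11 CPM in uninjured skin and 8.81 ± 1.48 against 16 ± 1.54 in injured skin. The T and natural killer median ran from -0.434 to -0.192 over those fits. By skin state, the list median was -0.509 in uninjured and -0.103 in injured skin, where Cd8a went the other way. Cd8a was at 0.962, 0.564 and 1.291 CPM in Nf1-KO injured libraries and at 0, 0.127 and 0.134 in control injured ones. Of 18 muscle genes, 0 were positive (median -0.95, adjusted p = 1.36e-17, and adjusted p = 0.297 with an estimated correlation), with a median of -0.487 without control injured 2. The muscle call came from uninjured skin, where the median was -1.75, while in injured skin it was -0.21 and the list was not called (adjusted p = 0.15). Other Schwann lineage genes were positive in 17 of 20 cases (median 0.36, adjusted p = 0.011, and adjusted p = 0.676 with an estimated correlation). That call was lost without Nf1-KO injured 3 (median 0.16, adjusted p = 0.12), control uninjured 3 (median 0.284, adjusted p = 0.0718) or control injured 1 (median 0.371, adjusted p = 0.0626), and with the ribosomal RNA-like covariate (median 0.232, adjusted p = 0.137). Its median was larger without control injured 2 (0.546, adjusted p = 7.09e-05) and without the 2 highest-background libraries (0.644, adjusted p = 0.0114). The remaining calls were sebaceous (median 0.44), adipocyte (-0.24), basal (-0.23), differentiating (-0.28) and wound-activated keratinocyte (-0.17), endothelial (-0.11), myofibroblast (-0.15) and immediate early genes (-0.14), with adjusted p from 0.301 to 0.676 with an estimated correlation. With 1 library left out, the differentiating (median -0.393 to -0.223) and basal calls (-0.349 to -0.153) were kept in all 12 fits, and the basal median was -0.469 without the 2 highest-background libraries. The wound-activated call was lost in 6 (median -1.355 to 0.926), the endothelial in 5 (-0.311 to -0.006), the myofibroblast in 4 (-0.301 to 0.066), the immediate early in 3 (-0.273 to -0.032), the adipocyte in 2 (-0.481 to -0.058) and the sebaceous in 1 (0.248 to 0.646). The filter of 2 CPM in 3 samples lost the wound-activated (median -0.214, adjusted p = 0.144), myofibroblast (-0.203, adjusted p = 0.132), immediate early (-0.183, adjusted p = 0.0716) and endothelial calls (-0.17, adjusted p = 0.0538), although these shifts were no smaller. Subtraction of background (medians -0.22 and -0.213, adjusted p = 0.099 each) and median-of-ratios scaling (-0.244 and -0.234, adjusted p = 0.0657 and 0.0599) lost the wound-activated and myofibroblast calls, again with shifts no smaller. The ribosomal RNA-like covariate lost the adipocyte call (median -0.089, adjusted p = 0.0703). Without the 2 highest-background libraries the sebaceous (0.25, adjusted p = 0.324), endothelial (0.011, adjusted p = 0.271) and adipocyte calls (-0.133, adjusted p = 0.0639) were lost. Calls were kept there with medians of -0.755 for wound-activated, -0.351 for myofibroblast and -0.173 for T and natural killer genes, and with the covariate at -0.464 for wound-activated and -0.146 for basal genes. Calls were also kept for immediate early genes after subtraction (-0.267) and with the replicate block (-0.26), for myofibroblast genes with that block (-0.089), and for endothelial genes after subtraction (-0.173) and with median-of-ratios scaling (-0.186).

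Genes near the end of chromosome 1 differed between genotypes more often than others in injured skin. From 140 Mb on, 85 of 552 genes had unadjusted p under 0.05, against 2447 of 23083 elsewhere (odds ratio 1.53, 1.2 to 1.95, Fisher's exact p = 0.000614). DNA of another strain in this region could raise such a share, since the labels name C57BL/6 and B6D2 as the strain, but it would do so in both skin states. In uninjured skin the odds ratio was 1.0 (0.72 to 1.36). This argues against strain DNA common to the Nf1-KO mice that raises the share across the region in both skin states. It leaves open strain DNA behind single genes. Glul, Teddm2, Mir8114 and Srp9, called in uninjured skin, lie in this region. DNA that differs between the mice of each group was not tested. Neighbouring genes are not independent, so these p-values are likely too small. The tests by region and by chromosome used counts without subtraction of background. That background was higher in Nf1-KO injured 2 and 3 (0.0141 and 0.0425 CPM per kb) than in control injured libraries (at most 0.00503). After subtraction, 1802 genes of injured skin had unadjusted p under 0.05, against 2532 before it. Whether background raised the share on chromosome 1 was not tested. By whole chromosomes, with p adjusted over 20 chromosomes, the odds ratio in uninjured skin was 1.63 on chromosome 19 (adjusted p = 0.00189), 1.46 on chromosome 17 (0.00535), 1.25 on chromosome 11, which carries Nf1 (0.0448), and 0.74 on chromosome 1 (0.02). In injured skin it was 1.4 on chromosome 1 (adjusted p = 0.000268), 1.39 on chromosome 14 (0.00716), 1.33 on chromosome 7 (0.000769) and 1.28 on chromosome 6 (0.0106), and 0.73 on chromosome 11 (0.00223) and 0.6 on chromosomes 16 (0.00282) and 18 (0.00743). The other chromosomes had adjusted p over 0.05.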
